A study of Zea mays with 12 samples.

How the data were processed

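Poly(A) RNA of primary roots of maize B73 seedlings was sequenced in 12 samples, 3 in each of 4 groups: N-deprived control, nitrate, N-deprived with TIS108, and nitrate with PCIB. Groups were taken from the sample titles. Per the labels' protocols, RNA was extracted with a plant total RNA kit and paired-end libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, CASAVA 1.8, Trimmomatic 0.39 and TopHat2 2.0.13 and the genome build B73 RefGen_v4 were used, with no role or order given. The program that computed the expression values, the annotation release, the treatment of strand and any filter on genes are not given in the sources used here.

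The authors deposited 1 table of FPKM values (fragments mapped to a transcript, scaled by its length and by the total of mapped fragments) with 1 column per group. Per the file headers the columns are named for the treatments. Each column was used as the authors' value for its group, and how the 3 replicates were combined is not given in the sources used here. FPKM depends on the annotated length of a feature and on the total of mapped fragments, so that values of short features are less stable and a few abundant transcripts change all other values of a column. The table had 26451 entries, of which 11 were listed at 0 in any column (12 of 105804 values). The lowest maximum over the groups was 0.032 FPKM. The first 11467 entries were rounded to 3 decimals and the other 14984 carried up to 9. All 4 values were shared with another entry by 78 entries, and each of the 25 microRNA loci had an ENSRNA entry with identical values, so reads over overlapping entries cannot be told apart here. Depth is unknown, since the table gives no counts, and no interval or detection limit could be computed. There were 0 columns that belonged to no group.

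The plan fixed before the data were examined was limma on log2(FPKM + 1) over replicates. With 1 value per group no such test could be run, and the plan's rule for this case was used: a difference was counted when it was at least 2-fold with 5 FPKM or more in the higher group. Folds for this limit were taken on the log2(FPKM + 1) scale, with a pseudocount of 1, which understates differences of low entries. Ratios printed beside FPKM values are plain ratios of FPKM. No difference was called significant, and 0 tests across replicates were made.

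Names came from the identifiers in the table and from a RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone because its build differs from that of the data; no coordinates were taken from it. Of all identifiers 97 matched (the microRNA loci and organelle genes), and 0 of the 26061 nuclear gene models. The 30 gene lists fixed in advance, written for nuclear genes in the main, could therefore not be filled; the 2 photosystem genes psbA and psaB are given as single genes. By the rule fixed in advance, each comparison names the 2 nuclear identifiers with the widest difference in each direction and up to 8 named features per direction that met the limit. The sets of microRNA loci, mitochondrial genes, plastid genes and ENSRNA entries, and other examples within them, were chosen after the data were seen.

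For each such set the number above and below and the median log2 difference were taken, with entries of identical values in all 4 columns counted once. Entries alike in only some of the columns, such as the plastid rpl23 copies, were each counted. The median was placed among 10000 random lists of nuclear gene models of the same size, matched on mean level in 20 bins. This percentile describes the columns and is no test across replicates. List members were drawn independently. A set whose entries vary together has a more variable median than such lists, so extreme percentiles may overstate how unusual a set is. Single microRNA loci were placed among the 1000 nuclear gene models nearest in mean level. For the numbers of differing entries and for comparisons that share a column, 100 simulations of 4 unchanged groups were drawn around each entry's mean level, with noise resampled within 100 bins of mean level from the nitrate and TIS108 difference divided by the square root of 2. Overlaps were compared with simulated lists of the observed length, added after the results were seen. This treats the whole difference of that pair as noise and assumes equal noise in all columns, which the data cannot check. That pair had the narrowest spread of all pairs of groups (SD 0.32), and its difference also holds any response in which nitrate and TIS108 differ. Calling was tested on simulated data with that noise for the comparison of TIS108 with nitrate over 26451 entries with 200 changed, drawn from entries with a mean of 10 FPKM or more: 99.5% of entries changed 4-fold were recovered, 52.0% of those changed 2-fold, and 1.08% of the unchanged entries at 5 FPKM or more were called in the 2-fold run.

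Alternatives were other pseudocounts (0.1 and 5), no minimum level or a mean of 5 FPKM over the groups, columns rescaled to the same sum, median-of-ratios scaling and quantile normalization. Plain FPKM ratios and counting identical entries once were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.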

Results

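The transcriptome of primary roots of maize seedlings, inbred line B73, was profiled by sequencing of poly(A) RNA after 24 h of growth in 4 nutrient solutions. Seedlings that had germinated for 3 days received a solution without nitrogen (the N-deprived control), 1 mM nitrate, the solution without nitrogen plus 2 µM TIS108, or 1 mM nitrate plus 10 µM PCIB. TIS108 is a triazole-type inhibitor of the synthesis of strigolactones, carotenoid-derived hormones, and PCIB is p-chlorophenoxyisobutyric acid, an inhibitor of auxin action. Each group had 3 biological replicates of 4 to 8 plants, 12 samples in all, but the values analysed here are 1 FPKM value per entry and group. Every difference below therefore has no replicate check: there is no SD, standard error or p-value, and differences are descriptions of these 4 columns. The sequencing depth of each library is unknown.

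The table held 26451 entries: 26061 nuclear gene models, 293 entries with an ENSRNA identifier (RNA genes annotated by Ensembl), 25 microRNA loci, 57 mitochondrial entries and 15 plastid entries. Summed FPKM was 497447 in the N-deprived control, 469344 with nitrate, 447300 with TIS108 and 483955 with nitrate plus PCIB. At least 5 FPKM was reached by 14929 entries in the control, 14535 with nitrate, 14576 with TIS108 and 14836 with nitrate plus PCIB. Nuclear gene models are given below by identifier because none of them could be paired with a gene name here, so genes of nitrate assimilation, strigolactone synthesis or auxin response could not be picked out. The named features are the microRNA loci and the organelle genes. A difference was counted when it was at least 2-fold on the FPKM + 1 scale with 5 FPKM or more in the higher group.

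The first comparison addressed the response of roots to nitrate. With nitrate, far more entries were lower than higher by the 2-fold limit than in the N-deprived control: 536 were lower and 87 higher among 15510 entries at 5 FPKM or more in either group. The median log2 difference over all 15510 was 0.05, so the typical FPKM value was not lowered. FPKM is relative to the total of its column, so a general change of transcript amount would not be seen here. Simulations of 4 unchanged groups, described with the processing, gave 91.9 lower (range 66 to 117) and 94.4 higher (range 73 to 116), so the number of higher entries did not exceed them. This does not show that the higher entries are noise, because the simulated noise is the difference between nitrate and TIS108. In that difference 58 of the 87 entries were themselves at least 2-fold apart. The few higher entries included the widest differences, since 23 were higher by at least 4-fold and 2 by at least 16-fold, whereas 34 were lower by at least 4-fold and 0 by 16-fold. Zm00001d045022 stood at 0.0465 FPKM in the control and 25.4 FPKM with nitrate, and Zm00001d048020 at 5.21 and 109 FPKM. At the other end, Zm00001d044769 stood at 46.5 FPKM in the control and 5.37 FPKM with nitrate, and Zm00001d003380 at 7.03 and 0.184 FPKM. The median over the 87 higher entries was 4.48 FPKM in the control and 16.5 FPKM with nitrate, and that over the 536 lower entries was 13.2 and 4.40 FPKM.

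Among the microRNA loci, 2 were higher and 1 lower with nitrate by the 2-fold limit. MIR169c, of a family that targets NF-YA transcription factor genes, was at 2.65 FPKM in the control and 8.66 FPKM with nitrate, a ratio of 3.27. MIR408b, of a family that targets genes of copper proteins, was at 2.20 and 5.56 FPKM, a ratio of 2.52. MIR398b, of another copper-linked family, was the lower locus, at 5.09 and 1.75 FPKM. Of the loci short of the limit, the widest differences upward were those of MIR167g, whose family targets auxin response factor genes, at 2.60 and 5.73 FPKM, and MIR166d, whose family targets class III HD-ZIP genes, at 5.58 and 11.3 FPKM. The widest downward were those of MIR156k, whose family targets SPL transcription factor genes, at 12.8 and 6.38 FPKM, and MIR159d, at 1.19 and 0.706 FPKM. The 25 loci as a set were split, with 12 above and 13 below the control and a median log2 difference of -0.01, against 16 above and 9 below after quantile normalization. The difference of MIR169c exceeded that of 100% of the 1000 nuclear gene models nearest in mean level, and that of MIR167g exceeded 99.2% of its own. With a pseudocount of 5 the differences of MIR169c, MIR408b and MIR398b fell short of the limit, at log2 values of 0.84, 0.55 and -0.58. These are reads over loci in a poly(A) library, not mature microRNAs, and each locus shares its values with an ENSRNA entry. Apart from the MIR169c, MIR408b and MIR398b loci, the examples were chosen after the values were seen.

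**Figure D1:**
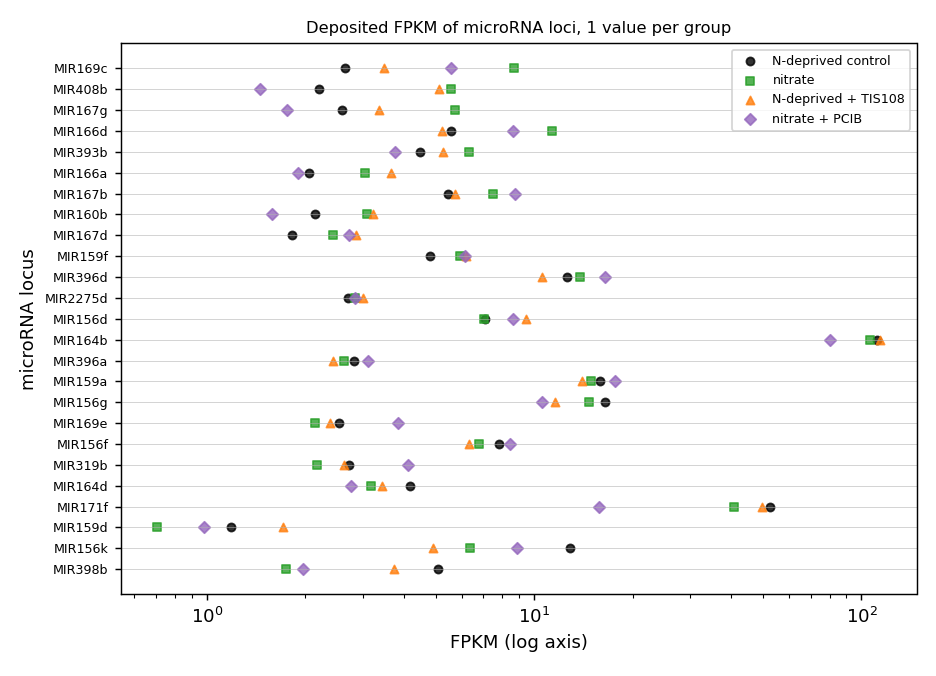
FPKM (log axis) of the 25 microRNA loci in the 4 groups, 1 deposited value per group and no error bars, ordered by the log2 difference between nitrate and the N-deprived control. The highest of the 4 values of MIR169c is that with nitrate, 8.66 FPKM, and the lowest of MIR171f is that with nitrate plus PCIB, 15.8 FPKM.

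Mitochondrial genes as a set differed little between nitrate and the control, while most plastid genes were slightly above it. Of 56 mitochondrial entries with distinct values, 31 were above and 25 below the control, and 0 reached the 2-fold limit. The median log2 difference was 0.04, at percentile 96.45 of its random lists, and 41 entries were above the control after quantile normalization. The 3 cytochrome c oxidase genes cox1, cox2 and cox3 were all slightly above the control, with a median ratio of 1.22, and rps12, a ribosomal protein gene, was at 85.0 FPKM in the control and 60.6 FPKM with nitrate. Plastid genes were at low levels, and 14 of 15 were above the control, with a median log2 difference of 0.16 that exceeded 99.9% of 10000 random lists of nuclear gene models matched on mean level. That median is the value of the rpl23 copies, which share their control and nitrate levels and were both counted. The random lists also take entries as independent, which plastid genes may not be. The photosystem genes psbA and psaB, markers of green tissue, were at 0.487 and 0.117 FPKM in the control and at 0.609 and 0.0999 FPKM with nitrate.

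The second comparison asked how roots without nitrogen respond when strigolactone synthesis is inhibited. Against the N-deprived control, 284 entries were lower and 3 higher with TIS108 among 15381 entries at 5 FPKM or more, and 27 were higher when columns were rescaled to the same sum. The simulations of unchanged groups gave 92.9 lower (range 69 to 112) and 95.0 higher (range 71 to 122). The 3 higher entries lay far below that range, so the symmetric simulations describe this comparison poorly. The 284 lower entries therefore cannot be judged by them. The 284 entries were not low with TIS108 alone: 281 of them (98.9%) were also below the control with nitrate and 255 (89.8%) with nitrate plus PCIB, where sets chosen in the same way from the simulated groups had 75.8% to 92.0% and 71.9% to 93.6%. Zm00001d008523 stood at 92.2 FPKM in the control and 8.78 FPKM with TIS108, and Zm00001d001572 at 17.5 and 1.56 FPKM. The widest differences upward were small, with Zm00001d011472 at 3.05 and 7.25 FPKM and Zm00001d050557 at 5.38 and 11.8 FPKM. No entry was higher by 4-fold and 7 were lower by 4-fold. The median over the 284 lower entries was 16.1 FPKM in the control and 6.0 FPKM with TIS108.

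Mitochondrial genes were lower with TIS108 than in the control as a group: 50 of 56 were below it, with a median log2 difference of -0.26 and a median FPKM ratio of 0.708. None of 10000 matched random lists of nuclear gene models had a median as low, and 95% of these lists lay between -0.13 and 0.04. The lists were drawn as if entries varied independently, which mitochondrial entries may not. The percentiles of mitochondrial sets given here may therefore overstate how unusual they were. Only 12 of the 56 reached 5 FPKM in either group, and all 12 were lower, with a median of -0.95. Some of the 12, such as trnR-a at 5.83 and 2.64 FPKM, passed this level only through the control. Such entries are lower by the choice, so the direction and median of the 12 are in part built in. Against nitrate, 51 of 56 were lower with TIS108, with a median of -0.37, again below all 10000 random lists. The sets of respiratory genes were small, and against the control each median lay within the central 95% of its own random lists. Against nitrate all 3 medians lay below it. They were -0.37 for NADH dehydrogenase genes (percentile 0.07), -0.45 for ATP synthase genes (percentile 0.01) and -0.45 for cytochrome c oxidase genes (percentile 0.21). All 5 NADH dehydrogenase genes were lower than in the control (median log2 difference -0.38, percentile 4.41), among them nad3 at 19.6 FPKM in the control and 10.7 FPKM with TIS108, as were all 5 ATP synthase genes (median -0.24, percentile 11.4), among them atp9 at 45.8 and 22.5 FPKM (4 of 5 when columns were rescaled to the same sum), and all 3 cytochrome c oxidase genes (median -0.21, percentile 19.1). After quantile normalization these medians were -0.26, -0.10 and -0.10, and that of cytochrome c oxidase was also -0.10 with columns rescaled. Of the 10 mitochondrial ribosomal protein genes 7 were lower than in the control, with a median of -0.07 at percentile 51.1 of its random lists, and the median was 0.02 after quantile normalization. The largest subset, 22 mitochondrial open reading frames, lay below the central 95% of its random lists (-0.19 to 0.08). Of these 20 were lower, with a median of -0.30 at percentile 0.1. By the 2-fold limit 5 mitochondrial entries were lower, namely trnL-b at 18.0 and 5.14 FPKM, rrn5 at 13.4 and 5.61 FPKM, rps12 at 85.0 and 39.8 FPKM, and orf99-b1 and orf99-b2, both at 6.80 and 2.72 FPKM. The orf99-b1 and orf99-b2 entries share these values and were both counted, also among the 12. As with the microRNA loci, organelle and ENSRNA values are reads in a poly(A) library, and trnL-b and rrn5 are a tRNA and a ribosomal RNA. How far the selection of poly(A) RNA shaped these values is unknown. ENSRNA entries were lower as well, with 184 of 268 below the control and a median log2 difference of -0.17, which was -0.04 with columns rescaled to the same sum, where the median of all entries was 0.12. The mitochondrial median was -0.45 with a pseudocount of 0.1, -0.10 with a pseudocount of 5 and -0.15 after quantile normalization, and rps12 fell short of the limit with columns rescaled to the same sum (-0.93) and after quantile normalization (-0.96). With a pseudocount of 5 the differences of rrn5 and of orf99-b1 and orf99-b2 fell short of it too, at -0.79 and -0.61.

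**Figure D2:**
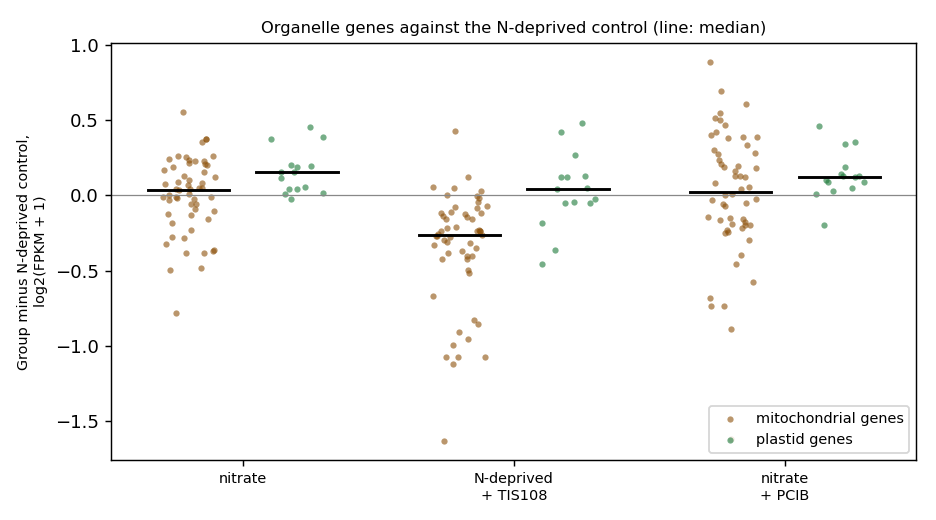
Log2 differences (FPKM + 1) of each group from the N-deprived control for 56 mitochondrial and 15 plastid entries; each point is an entry and each black line the median of its set. The mitochondrial median lies at -0.26 with TIS108 and at 0.04 with nitrate.

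Plastid genes did not follow the mitochondrial ones under TIS108, with 8 of 15 above the control and a median log2 difference of 0.04. petA, a gene of the cytochrome b6f complex, was at 3.73 FPKM in the control and 5.58 FPKM with TIS108, and clpP, a protease gene, at 1.37 and 0.724 FPKM. The microRNA locus MIR156k was lower by the 2-fold limit at 12.8 FPKM in the control and 4.92 FPKM with TIS108. MIR408b was at 2.20 and 5.13 FPKM, short of the limit on the FPKM + 1 scale, and MIR169c was at 2.65 and 3.49 FPKM. With a pseudocount of 5 the difference of MIR156k was -0.85. Of the 25 microRNA loci 13 were above and 12 below the control, and 17 and 8 with columns rescaled to the same sum.

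The responses to nitrate and to TIS108 were then set side by side, to see how far the inhibition of strigolactone synthesis resembles the supply of nitrate. The lower lists shared 157 entries, which are 29.3% of the entries lower with nitrate, and the higher lists shared 1. Both comparisons use the same control column, so an overlap arises without any effect. Lists of the same length, taken as the widest differences in each of 100 simulations of unchanged groups, shared 138.0 entries on the lower side (range 114 to 157) and 1.30 on the higher side (range 0 to 3). The 157 thus lay at the top of the simulated range and not above it, and 1 of the 100 simulations reached it. By the 2-fold limit itself the simulated lower lists, which were shorter, shared 33.45 entries (range 22 to 49). The simulated share of the nitrate list was then 36.4% (range 27.2% to 48.2%). As a share of the TIS108 list the overlap was 55.3%, above the simulated range of 24.0% to 51.0%, although the observed nitrate list is far longer than the simulated ones, which raises this share. The lists therefore do not settle whether the overlap exceeds that of a shared control. The simulations are symmetric and these columns are not, so they describe the lists only roughly. The simulated spread was taken from the difference between nitrate and TIS108 treated as noise alone. Across 15231 entries, which are not independent replicates, the log2 differences had a Pearson r of 0.71 and a covariance of 0.098, both above every simulation (0.47 to 0.55 and 0.045 to 0.053). Both comparisons with the control had a wider spread (SD 0.43 and 0.34) than the pair used as noise (SD 0.32). This by itself lifts both values above the simulated averages, so they cannot tell a shared response from a control column that stands apart. The controls could not be split, as there is 1 control column, and part of the excess may come from it.

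The side on which nitrate gave higher levels was not matched by TIS108. Over the 87 entries higher with nitrate, the median log2 difference was 1.49 with nitrate and 0.15 with TIS108, and 58 of them (66.7%) were lower by at least 2-fold with TIS108 than with nitrate. Sets chosen in the same way from the simulated groups gave medians of 0.30 to 0.79 for the value with TIS108, and shares of 25.3% to 46.1%. Zm00001d048020 was at 109 FPKM with nitrate and 4.18 FPKM with TIS108, and Zm00001d045022 at 25.4 and 0.116 FPKM. Over the 536 entries lower with nitrate the median was -1.29 with nitrate and -0.77 with TIS108, and 513 of them (95.7%) were below the control with TIS108. Such sets share the control column with their choice, and those from unchanged groups gave medians of -0.96 to -0.43 and shares of 76.9% to 93.6%, so the median lay within the simulated range and the share above it. In the direct comparison of TIS108 with nitrate, 114 entries were higher and 90 lower among 15066. The lower share was 44.1% of these entries, 29.4% when each column was rescaled to the same sum, and 58.8% with a pseudocount of 5, so the direction depended on the setting. Zm00001d003380 stood at 0.184 FPKM with nitrate and 7.79 FPKM with TIS108, and Zm00001d043344 at 2.84 and 22.3 FPKM. MIR169c, at 8.66 FPKM with nitrate and 3.49 FPKM with TIS108, and rrn5, at 13.1 and 5.61 FPKM, were lower with TIS108, though short of the limit with a pseudocount of 5 (-0.69 and -0.77). Of the 6 pairs of groups, nitrate and TIS108 had the narrowest spread of log2 differences (SD 0.32 across 16001 entries) and nitrate and nitrate plus PCIB the widest (SD 0.49).

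**Figure D3:**
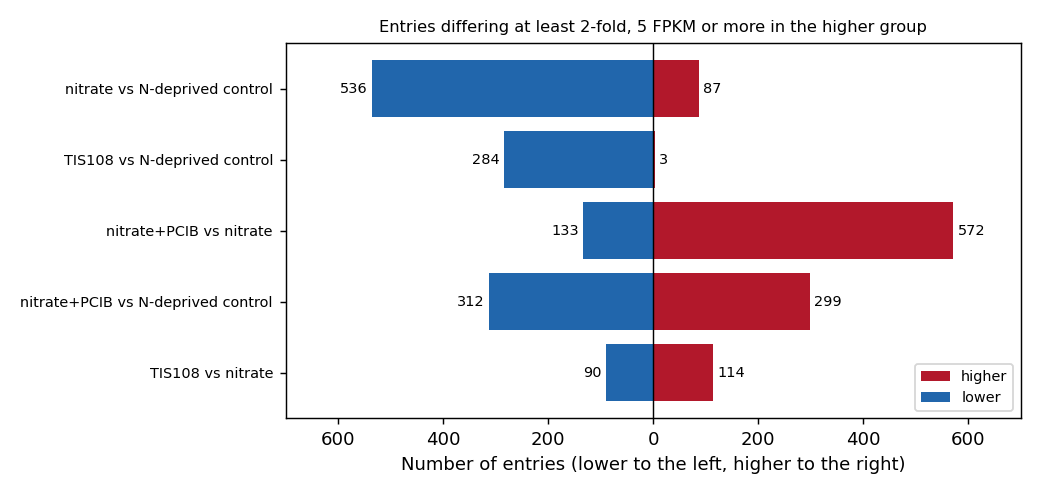
Number of entries higher (right) and lower (left) by at least 2-fold on the FPKM + 1 scale, with 5 FPKM or more in the higher group, in each of the 5 comparisons. Lower entries prevail with nitrate (536 against 87) and TIS108 (284 against 3), and higher entries when PCIB is added to nitrate (572 against 133).

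The third comparison set roots given nitrate and the inhibitor of auxin action against roots given nitrate. No group had PCIB without nitrate, so an effect of PCIB of its own is not separated here from a part of the nitrate response that needs auxin action. Of the entries past the 2-fold limit most were higher when PCIB was added to nitrate, with 572 entries higher and 133 lower than with nitrate alone among 15447 entries at 5 FPKM or more, against simulated ranges of 72 to 121 and 79 to 129. The median log2 difference over all 15447 was -0.05, so the typical FPKM value was not raised, which again says nothing of total transcript amount. On the FPKM + 1 scale the upward differences were the widest in the study, as 124 entries were higher by at least 4-fold and 14 by at least 16-fold. Downward, 11 entries were lower by at least 4-fold, against 34 for nitrate over the control. Zm00001d007285 stood at 0.477 FPKM with nitrate and 179.7 FPKM with nitrate plus PCIB, a ratio of 377, and Zm00001d051251 at 1.95 and 259 FPKM, a ratio of 133. As a plain ratio of FPKM, that of Zm00001d045022 between nitrate and the control, 546, was wider. On the lower side, Zm00001d047907 stood at 8.75 and 0.592 FPKM and Zm00001d007160 at 13.3 and 2.08 FPKM.

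The microRNA loci past the limit with PCIB were 3, all lower. MIR171f, whose family targets GRAS transcription factor genes, was at 40.8 FPKM with nitrate and 15.8 FPKM with nitrate plus PCIB, a difference that exceeded only 0.10% of those of the 1000 gene models nearest in mean level. It was at 52.4 FPKM in the control and 49.6 FPKM with TIS108. MIR167g was at 5.73 and 1.76 FPKM and MIR408b at 5.56 and 1.45 FPKM, so that both lay below the control when PCIB was present. Of the loci short of the limit, the widest differences downward were those of MIR160b, at 3.09 and 1.59 FPKM, and MIR393b, at 6.31 and 3.75 FPKM, and the widest upward those of MIR319b, at 2.17 and 4.11 FPKM, and MIR169e, at 2.14 and 3.83 FPKM. With a pseudocount of 5 the log2 differences of MIR408b and MIR167g were -0.71 and -0.67, short of the limit. MIR164b, the locus with the highest level, was at 106 and 80.2 FPKM; its family targets NAC genes. Over all 25 loci 14 were above and 11 below nitrate. Over the full set, mitochondrial genes were not displaced by PCIB, with 29 above and 27 below nitrate and a median log2 difference of 0.01, which was -0.09 after quantile normalization. Only 16 of the 56 reached 5 FPKM in either group, and more of these were lower than higher. Among them trnL-b was at 10.0 and 5.19 FPKM, atp9 at 42.9 and 24.3 FPKM and rrn5 at 13.1 and 7.96 FPKM. In the other direction, orf99-d was at 8.71 and 13.9 FPKM. ENSRNA entries were lower, with 228 of 268 below nitrate and a median of -0.43.

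Of the 536 entries lower with nitrate than in the control, 171 were also in the list of entries higher with PCIB by the 2-fold limit, and 490 (91.4%) were above their nitrate level by any amount, with a median log2 difference of 0.69. Sets chosen in the same way from the simulated groups had 71.4% to 89.2% above and medians of 0.25 to 0.83, so the median lay within the simulated range and the share above it. The nitrate column enters both comparisons with opposite signs, so the 171 are above 0 by construction: simulated lists of the same length shared 159.0 on average (range 141 to 191), so the number shared lay within that range. On the other side, 29 of the 87 entries higher with nitrate were lower by the limit with PCIB, within the range of 25 to 48 for such lists (mean 37.9). The 87 entries were above the N-deprived control in 71 cases (81.6%) with nitrate plus PCIB, with a median log2 difference of 0.98 against 1.49 with nitrate alone. The simulated sets gave 74.2% to 89.9% above and medians of 0.22 to 0.82, so the median lay above their range and the share within it. The covariance of the 2 sets of differences across 15038 entries was -0.099 and Pearson's r was -0.57, both further from 0 than in every simulation (-0.053 to -0.045 and -0.55 to -0.49). The simulated noise came from the pair with the narrowest spread and was equal in all columns. These values therefore cannot tell a response from wider noise in the other columns.

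**Figure D4:**
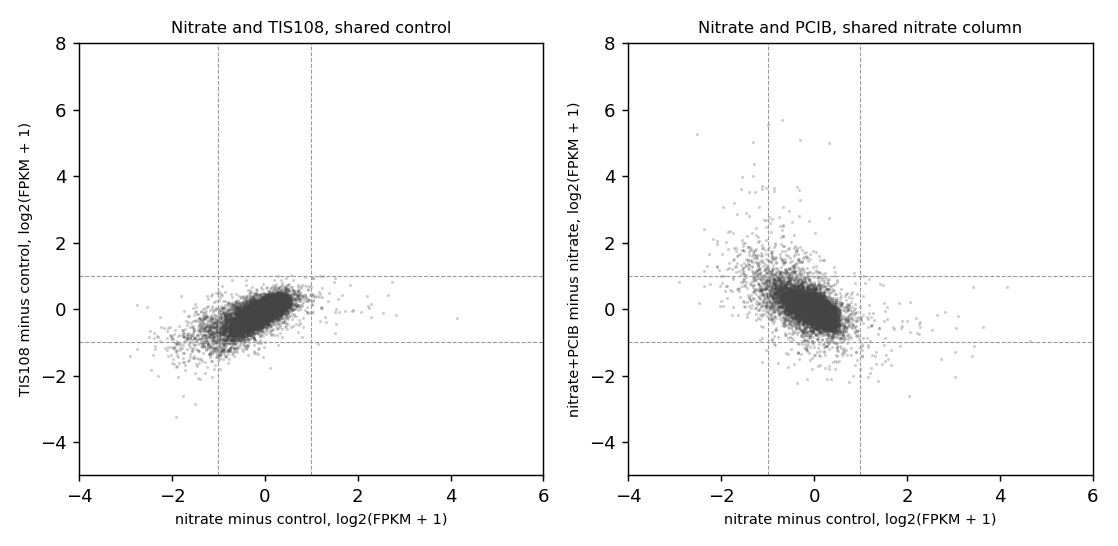
Log2 differences (FPKM + 1) per entry, with dashed lines at the 2-fold limit. Left, TIS108 minus control against nitrate minus control for 15231 entries (r 0.71); right, nitrate plus PCIB minus nitrate against nitrate minus control for 15038 entries (r -0.57), in both cases with 5 FPKM or more in each comparison and with a column shared between the axes.

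Against the N-deprived control, nitrate plus PCIB gave 299 higher and 312 lower entries among 15622, a lower share of 51.1% that was 38.7% with a pseudocount of 5. This comparison holds nitrate and PCIB together. Zm00001d007285, at 0.614 FPKM in the control and 179.7 FPKM with nitrate plus PCIB, and Zm00001d051251, at 1.97 and 259 FPKM, had the widest differences here too. Zm00001d037894, at 41.3 and 5.55 FPKM, and Zm00001d007160, at 17.5 and 2.08 FPKM, were at the lower end. MIR171f, at 52.4 and 15.8 FPKM, MIR398b, at 5.09 and 1.97 FPKM, and the mitochondrial trnL-b, at 18.0 and 5.19 FPKM, were lower by the limit, MIR398b not so with a pseudocount of 5 (-0.53). MIR169c was at 5.58 FPKM with nitrate plus PCIB, between its levels in the control and with nitrate. Of the mitochondrial genes 30 were above and 26 below the control, and of the plastid genes 14 of 15 were above it.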

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

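No paired analysis was possible because the table holds 1 value per group and no replicate; for the same reason the planned fits with a replicate block, a replicate left out, only the compared groups, no trend in the spread, library weights or a fold limit beside a p-value were not run, nor were the gene list tests. Over all alternatives, 91 of 126 counts stayed within 1.5 times the reported count. No value of a named entry changed sign in 333 recomputations, and 16 of these came under the 2-fold limit, 14 of them with a pseudocount of 5. The unchanged signs are no check. Pseudocounts, plain ratios, level limits and counting identical entries once cannot reverse a sign, and the named entries were chosen for wide differences. Level limits do not enter the medians of entry sets either. Of 180 recomputed medians of entry sets 29 moved beyond the spread of their random lists. A pseudocount of 5 lowered every count: nitrate gave 50 higher and 189 lower entries, TIS108 gave 0 and 105, PCIB over nitrate 289 and 50, nitrate plus PCIB over the control 173 and 109, and TIS108 over nitrate 33 and 47; 39 entries were lower and 0 higher under both nitrate and TIS108, 54 were lower with nitrate and higher with PCIB, and 8 the reverse. A pseudocount of 0.1 gave 12 entries higher with TIS108 and 5 higher in both. Without a minimum level, 5 entries were higher with TIS108, 471 lower with nitrate plus PCIB than in the control, 172 higher with TIS108 than with nitrate, and 3 higher in both. With a mean of 5 FPKM required, 103 were lower in both and 15 higher with nitrate and lower with PCIB. Rescaling to equal sums, which also raises all values against the pseudocount and the minimum level, shifted the median of all entries for TIS108 minus control from -0.01 to 0.12, and gave 141 entries higher with nitrate, 27 higher with TIS108, 212 lower with PCIB than with nitrate, 495 lower with nitrate plus PCIB than in the control, 271 higher with TIS108 than with nitrate, 9 higher in both and 44 higher with nitrate and lower with PCIB. Median-of-ratios scaling gave 2 entries higher in both, and quantile normalization 8 higher with TIS108 and 5 higher in both. Plain ratios, added after the data were seen, gave 12 higher with TIS108, and 238 lower and 5 higher in both; counting identical entries once, added likewise, left all counts within 1.5 times. The cause of these shifts was not tested beyond what each setting itself does. In all these alternatives lower entries outnumbered higher ones with nitrate and with TIS108, and higher ones prevailed with PCIB over nitrate. The share of lower entries moved by over 10 points for nitrate plus PCIB against the control (38.7% with a pseudocount of 5) and for TIS108 against nitrate (58.8% with a pseudocount of 5). The unknown depth limits low entries most.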

Other observations

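Entries set apart in a single group were unevenly spread. Nitrate plus PCIB stood at least 2-fold above all 3 other groups in 191 entries and below them in 42, and the N-deprived control stood above all others in 69 and below in 1. The nitrate group stood below the others in 65 entries and above in 16, and TIS108 below in 5 and above in 0. Where 2 groups stood at least 2-fold apart from the other pair, nitrate and nitrate plus PCIB were above the control and TIS108 in 37 entries and below in 11, and nitrate and TIS108 were below the control and nitrate plus PCIB in 25 and above in 1. ENSRNA entries were above the control with nitrate in 188 of 268 cases, with a median log2 difference of 0.16, and below it with nitrate plus PCIB in 197, with a median of -0.24. None of the 10000 matched random lists reached either median, but these lists take entries as independent, which ENSRNA entries may not be.

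All tests below except that on equal levels of neighbouring entries were chosen after the result was seen. The 157 entries lower under both nitrate and TIS108 lay at the top of the range of 114 to 157 that lists of the same length share in simulated unchanged groups, so the shared control column without any effect stays open as their source. The r of both responses across entries, 0.71, lay above every simulation (0.47 to 0.55). The simulations assume equal noise in all columns and took it from the pair with the narrowest spread, so this r does not decide the question. The 157 entries would also arise if the N-deprived control alone were high in them: nitrate plus PCIB lay above the mean of nitrate and TIS108 in them by a median of 0.432 (log2), but an effect of PCIB of its own would give this too, so a high control stays open; nitrate plus PCIB was itself at a median of -0.92 from the control. A shared movement of nitrate and TIS108 is another candidate explanation: nitrate minus control and TIS108 minus nitrate plus PCIB, which share no column, had an r of 0.130 across 16001 entries, and the other such pairing had 0.22. A shared movement of the control and nitrate plus PCIB, or a shared handling of libraries, could give the same correlations, and neither was tested, because the labels name no batch.

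The lower level of mitochondrial genes with TIS108 is a hypothesis for follow-up. The gap to the median of all entries was -0.343, -0.254 and -0.204 under 3 other scalings. A factor on a column moves all entries together and changes this gap only through the pseudocount. Rescaling to equal sums and median-of-ratios scaling could thus hardly come out otherwise and are no independent checks. For the same reason a factor on the column does not by itself account for the gap. A high control alone is argued against by the median against nitrate, -0.371 over all 56 entries. The median was -0.54 over the 14 at 5 FPKM or more. Some of the 14, such as atp8 at 5.11 FPKM with nitrate and 2.35 FPKM with TIS108, passed only through nitrate. The median of the 14 is therefore in part built in and adds little. A lower yield of all organelle transcripts and one of short or non-coding features stay open: plastid genes had a median of 0.041, but 1 of 15 reached 5 FPKM (12 of 56 mitochondrial), and ENSRNA entries had a median of -0.173, against -0.26 for mitochondrial genes. Against nitrate, ENSRNA entries were as low as the mitochondrial set, with a median of -0.41 and 238 of 268 lower. Plastid genes had a median of -0.11 there, with 12 of 15 lower. With nitrate plus PCIB, ENSRNA entries were lower than the control (-0.24) while mitochondrial genes as a set were not (0.02), although the 14 at 5 FPKM or more had a median of -0.32 there. An effect of TIS108 itself may equally be the cause and was not tested, as the replicates are not separate here.

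Nuclear entries higher with PCIB than with nitrate were often neighbours in the table, with 51 pairs whose identifiers were at most 5 numbers apart, against a mean of 17.6 and a highest value of 32 in 1000 shuffles of the same calls. This excess of neighbours was not confined to that list: the pairs exceeded the highest shuffle in 7 of the 10 lists of entries higher or lower in a comparison. The lists share columns and entries, so they are not independent, and that of entries higher with TIS108 than in the control held only 3. The share of the 51 pairs with levels within 1.1-fold of each other in all 4 columns was 0 percent, which decides nothing, since FPKM is scaled by length and shared reads then give unequal levels. Reads shared in full would keep the ratio of a pair equal over the columns, but 3.92 percent of the pairs kept it within 1.1-fold, which argues against such sharing for most pairs. Local gene families that respond together, reads shared in part between near-identical copies, and neighbourhood effects may each contribute, and could not be separated without sequences.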
